A study of Mus musculus with 4 samples.

How the data were processed

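Total RNA was extracted from mouse livers with an RNeasy kit, combined by genotype and treatment, labelled with the Affymetrix WT Plus kit and hybridised to 1 array per group, per the labels' protocols. The authors deposited log2 expression values, 1 per probe set and array, for 41345 probe sets. Per the submitters' processing notes the values were made with affy and RMA, a method that subtracts background, normalizes arrays and summarises the probes of a set. The versions, the settings and whether the 4 arrays were normalized together are not given in the sources used here. The largest distance of an array's sorted values from the mean sorted values was 0.11, so the distributions are close without being identical. The values were used as deposited. RMA tends to compress large differences and those of dim genes. Array files hold no read depth. Array medians were 3.13 for chow WT, 3.17 and 3.12 for WT on fructose for 3 and 2 weeks, and 3.11 for Chrebp-null. Because RMA normalizes arrays, such close medians do not measure signal over background or the quality of an array.

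Probe sets were named from the platform annotation, which lists 1 gene symbol for 23521, several for 1814 and none for 16010. Entrez identifiers of 23328 of the first group were found in a table of the GRCm38.p6 assembly and changed 0 symbols. Probe sets with several symbols or none entered no gene-level value. For the 1082 genes with more than 1 probe set, the set with the highest mean over the 4 arrays was used, which left 22180 genes. All columns of per-sample values were used. No coordinates are reported, since no genome build is given with the values.

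Groups were taken from the labels. Because each group has 1 array, a difference is the log2 value of one array minus that of another, with no standard deviation and no p-value. A gene was assessed where the higher of the compared arrays was at or above a floor, the median over genes of the mean level (log2 3.52), and counted where the difference was at least 2-fold. The same count between the WT fructose pools served as a yardstick. For 44 gene lists of pathways, stress responses, cell types and sex-biased genes, the median difference of members above the floor was set beside the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The text gives the range from the 2.5 to the 97.5 percentile of those medians, which describes these arrays only. Overlaps of the comparisons are given beside the product of the counts divided by the number of genes assessed in both. Chance values for comparisons that share an array came from simulated unchanged genes.

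The floor, threshold, lists, comparisons and the rule for named genes were fixed before the data were examined. The rule takes Mlxipl, the 12 genes with the largest differences in each direction of each comparison (leaving out symbols without a described function and small non-coding RNAs), up to 4 members with the largest absolute difference of each list, and up to 10 genes per direction of the overlap. Not every gene it takes is printed. Where the dimmer array lay below the floor, a bound computed with that level set at the floor is given for most of the genes discussed with a difference past 2-fold.

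The procedure was tested on simulated arrays with noise of SD 0.303 per array, set from the spread of the difference between the WT fructose pools. The changed genes were drawn only from genes well above the floor, so recovery of genes near or below the floor was not examined. In the simulated fructose comparison 94.0% of genes changed 3-fold and 100.0% of those changed 4-fold were recovered among 11880 genes, and 2.50% of unchanged genes passed the threshold. In the simulated Chrebp-null comparison the values were 92.0%, 100.0% and 2.16% among 11941 genes. Of simulated lists of 15 unchanged genes, 3.50% lay outside the central range, and 92.0% of lists shifted by 0.50 did. Alternatives were no floor, a floor at the 75 percentile, arrays centred on their medians, quantile normalization, removal of the trend of the difference with level (lowess, fraction 0.3), the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, and the other WT fructose array or the mean of both in place of the main one. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.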

Results

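Liver RNA of C57BL/6 mice was measured on 4 Affymetrix expression arrays, 1 per group. Each array held RNA combined from several livers. The pools came from 7 wild-type (WT) mice on regular chow, 7 WT mice fed a diet of 70% fructose for 3 weeks, 4 WT mice fed that diet for 2 weeks, and 6 mice lacking Chrebp fed it for 2 weeks. ChREBP, encoded by Mlxipl, is a transcription factor that responds to sugar. Males and females were present in every pool, and their proportions are not given in the sources used here. The series design names 2 comparisons that share no array: fructose-fed WT (3 weeks) over chow-fed WT, called the fructose comparison, and Chrebp-null over WT after 2 weeks of fructose, called the Chrebp-null comparison. Array medians lay between 3.11 and 3.17 on the log2 scale, and Pearson's r between arrays over 41345 probe sets lay between 0.974 and 0.983. The pairs with the 2-week WT array had the lowest r, from 0.9743 to 0.9749. That array, the reference of the Chrebp-null comparison, had 10869 genes at or above the floor, against 11209 to 11239 on the others. Over genes above the floor the lowest r, 0.962, was between the 3-week WT and Chrebp-null arrays. There were no replicates, so no difference has a replicate check, no test was run, and the number of arrays limits the precision of every value. All differences are log2 differences between 2 arrays.

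The targeted gene was examined first. Mlxipl (probe set 17443185) read 9.25 in the chow pool, 9.64 and 9.83 in the WT fructose pools at 3 and 2 weeks, and 8.09 in the Chrebp-null pool. The null pool was thus lower than the 2-week WT pool by a log2 difference of -1.74, a ratio of 3.34, and lower than the 3-week WT pool by -1.55. The direction was that of the genotype label, with signal left above the floor of 3.52. Which part of the gene the probe set covers, and whether that part is deleted, is not given in the sources used here.

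The fructose comparison asks which liver genes differ after 3 weeks of fructose feeding. Genes of fatty acid synthesis were higher on fructose, and genes of cholesterol synthesis were lower. Among single genes, Pnpla3, which encodes a lipid droplet protein, was higher by at least 2.97 with its chow level of 3.12, below the floor, set at the floor (3.37 as read; probe set 17313677). Apoa4, an apolipoprotein, was higher by 3.00, Fabp5, a fatty acid binding protein, by 2.43, and Lepr, the leptin receptor, by 1.91. In the 2-week WT pool over chow Pnpla3 stood at 1.68 on the same terms, and the others at 2.21, 1.65 and 2.26. They were picked as largest in the first difference and the same chow array enters both, so this is not a separate check. In all, 75 genes were higher and 136 lower by at least 2-fold among the 11717 above the floor. After removal of the trend of the difference with expression level, 93 were higher and 105 lower.

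Of the 15 fatty acid synthesis genes above the floor, 2 were at least 2-fold higher and none was at least 2-fold lower. The median was 0.41, where random lists of matched expression gave medians between -0.25 and 0.09. Acaca, the cytosolic acetyl-CoA carboxylase, was higher by 1.20 and Me1, malic enzyme, by 1.18. Elovl6 and Acacb, a fatty acid elongase and the second carboxylase, were higher by 0.86 and 0.85. The 17 known ChREBP targets, of which 13 stand in another list too and 1 is Mlxipl itself, had a median of 0.49 (random lists -0.23 to 0.09), with Pnpla3 at least 2-fold higher. Fgf21, a liver hormone gene, read 2.92 on chow, below the floor. Its difference of 1.04 is 0.44 with that level set at the floor, under 2-fold. Lipoprotein genes had a median of 0.19 (random lists -0.26 to 0.12), and Apoa4 was the 1 gene of the 12 past 2-fold. With the 2-week pool over chow the medians were 0.49 for fatty acid synthesis, 0.77 for ChREBP targets and 0.23 for lipoprotein genes. Each lay above the range of its random lists, with the same chow array in both comparisons.

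Cholesterol synthesis and SREBP2 target genes had a median of -0.80 on fructose (random lists -0.23 to 0.10), and 9 of the 19 were at least 2-fold lower. Hmgcs1, which makes hydroxymethylglutaryl-CoA, was lower at -1.67 (probe set 17290173), Msmo1 at -1.57, Mvd at -1.34 and Cyp51 at -1.31. With the 2-week WT pool over chow the list median was -0.62, and 4 of those 9 genes stood at least 2-fold lower in both pools. Endoplasmic reticulum chaperones had a median of -0.25 (random lists -0.22 to 0.10), with Creld2 at -1.19 and Sdf2l1 at -1.04. Genes of the integrated stress response had a median of -0.30 (random lists -0.27 to 0.14), with Sesn2 at -1.05 as the 1 gene of 15 past 2-fold. With the 2-week pool over chow the median was -0.18, within the range of random lists (-0.23 to 0.13), and Sesn2 turned to 0.13.

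Xenobiotic cytochromes and conjugation genes were lower on fructose with a median of -0.32 (random lists -0.22 to 0.08). Of 20 genes, 4 were at least 2-fold lower, among them Cyp3a59 at -1.44, Cyp2c54 at -1.28 and Cyp2b10 at -1.17, and Cyp3a25 was higher by 1.29. Bile acid genes had a median of -0.40 (random lists -0.23 to 0.09), led by the transporters Abcc3 at -1.82 and Slco1a4 at -1.36, but with the 2-week WT pool the median was -0.04. The NRF2 and glutathione list had a median of -0.44 with no gene past 2-fold, and its median turned to 0.11 with the 2-week pool. In the growth hormone and insulin list, 3 of 13 genes were at least 2-fold lower: Igfbp1 at -2.01, Irs2 at -1.42 and Igfbp2 at -1.18. With the 2-week pool over chow Igfbp1 and Igfbp2 stood at -0.57 and -0.55, and only Irs2 stayed past 2-fold. The list median was -0.08 (random lists -0.27 to 0.13). With the 2-week pool over chow it was -0.25, below its range (random lists -0.18 to 0.15).

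Among the genes with the largest differences, a second group rested on the 3-week pool alone. The sulfotransferases Sult2a6, Sult2a3 and Sult3a2 were higher on fructose by 4.27, 2.33 and 2.16, and the cytochromes Cyp3a44 and Cyp3a16 by 2.46 and 1.99. In the 2-week WT pool Sult2a6, Sult2a3, Sult3a2 and Cyp3a16 read below the floor. With those levels set at the floor the last 3 stood at -0.61, -2.03 and -4.12 over chow, and Cyp3a44, above it, at -3.01, while Sult2a6 was below the floor on chow too. Akr1c18, a steroid dehydrogenase, was higher by 2.57, and read 3.53 on chow and below the floor in the 2-week pool, so it was not higher there. Acot2, an acyl-CoA thioesterase, was lower at -2.82 and stood at 0.31 there. These families hold similar copies, so array probes may not separate their members, and their values are uncertain. Sult2a6 read 2.00 on chow, and with that level set at the floor its difference is at least 2.75. Other genes lower on fructose included Ildr2 at -2.58, Atp6v0d2 at -2.13, Osgin1 at -1.98 and the nuclear receptor gene Nr4a1 at -1.96. The second probe set of Ildr2, near the floor, stood at 0.09.

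Most metabolic lists lay within the range of random lists in the fructose comparison. The medians were -0.02 for fructolysis, 0.05 for glycolysis, 0.05 for triglyceride synthesis and lipid droplets, 0.09 for gluconeogenesis, -0.09 for the pentose phosphate pathway, 0.04 for fatty acid oxidation and -0.13 for amino acid breakdown. With the 2-week pool over chow some of these lists lay above their ranges. Glycolysis stood at 0.31 (random lists -0.18 to 0.13), gluconeogenesis at 0.25 (-0.18 to 0.14) and triglyceride synthesis at 0.16 (-0.15 to 0.12). The other lists named stayed within range. Single genes in these lists still passed 2-fold in the fructose comparison, such as Cyp4a31 at 1.05 and Cth, the transsulfuration enzyme, at -1.01. Glycogen genes had a median of 0.16, at the edge of the random range (-0.28 to 0.15), and 0.24 with the 2-week pool (random lists -0.20 to 0.15). Male-biased liver genes had a median of 0.30 (random lists -0.24 to 0.13) and female-biased ones 0.14 (random lists -0.27 to 0.11), and with the 2-week pool over chow both turned, to -0.36 and -1.04. Xist stood at -0.07 in the fructose comparison and at -0.28 with the 2-week pool. The Y-linked genes Uty, Kdm5d and Eif2s3y stood at 0.64, 0.04 and -0.12, and at 0.84, 0.39 and 0.39 with the 2-week pool.

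These counts stand beside a yardstick. The 2 WT pools on fructose, which differ in weeks on the diet and in mice and are not replicates, differed by at least 2-fold in 276 genes, more than the 211 of the fructose comparison. With the floor at the 75 percentile that order turned, with 127 genes between the WT pools against 40 higher and 103 lower in the fructose comparison. Of the genes called in the fructose comparison, 16 were at least 2-fold higher and 22 at least 2-fold lower than chow in both WT pools. The same chow array enters both counts, and simulated unchanged genes with a shared chow array gave 15 and 21, about as many. The simulated noise was set from the difference of the WT fructose pools. At that noise 292 of 11680 unchanged genes passed 2-fold in the simulated fructose comparison, more than the 211 of 11717 called here. The simulated counts may therefore be too high, and these counts cannot tell whether the pools agree beyond a shared array. Among genes named above, Hmgcs1, Sdf2l1, Cyp3a25, Abcc3, Slco1a4, Ildr2, Cyp4a31 and Cth were under 2-fold with the 2-week pool over chow.

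**Figure D1:**
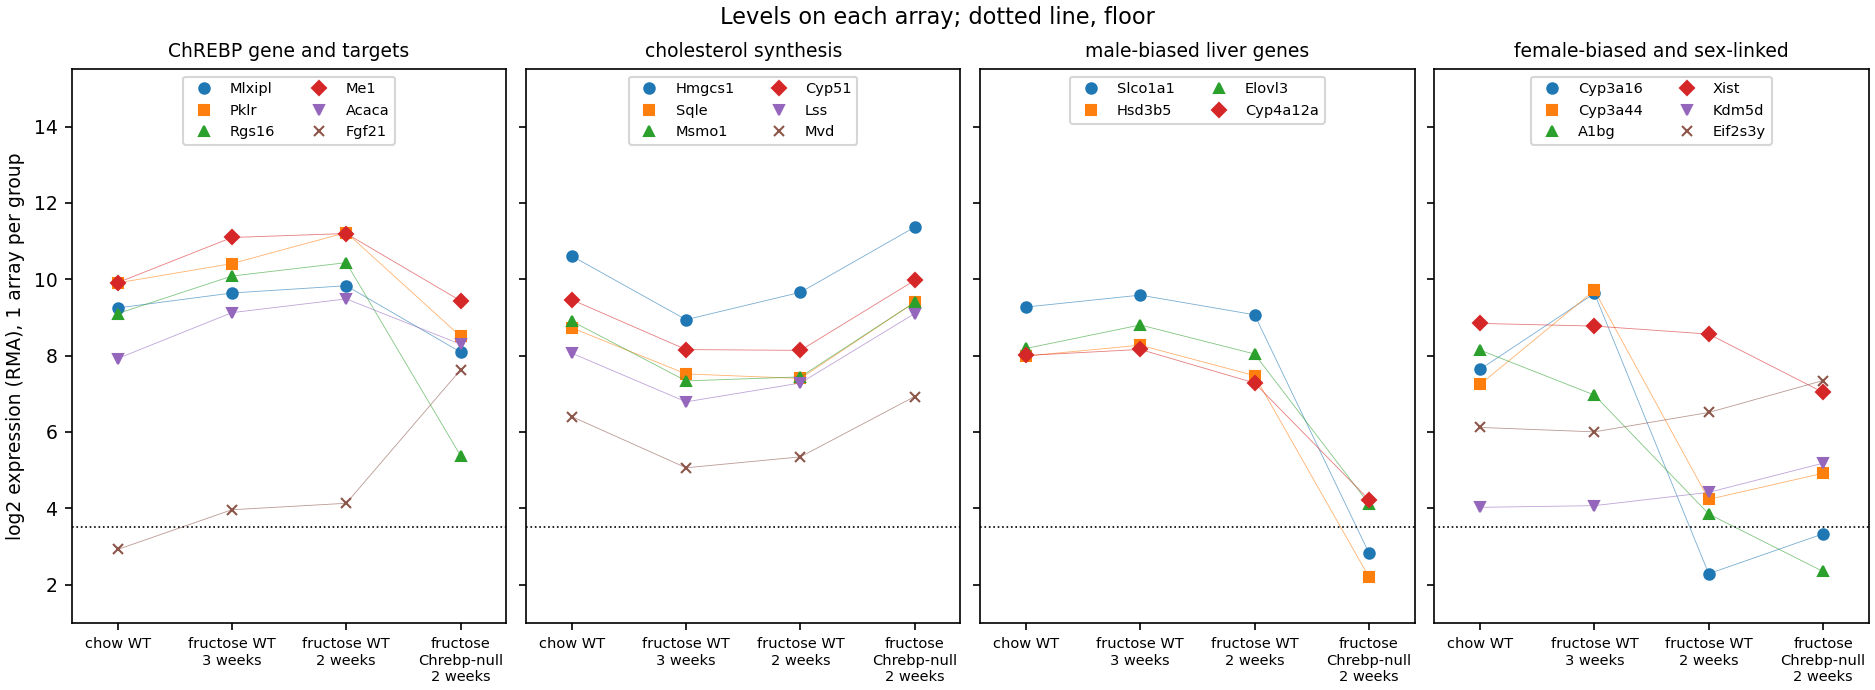
The log2 level (vertical axis) of each gene is plotted for each of the 4 arrays (horizontal axis), with thin lines only to guide the eye and a dotted line at the floor of 3.52. Slco1a1 reads between 9.07 and 9.58 on the 3 WT arrays and 2.83 on the Chrebp-null array, while Cyp3a16 reads 7.64 and 9.63 in the chow and 3-week pools and 2.28 and 3.33 in both 2-week pools.

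The Chrebp-null comparison asks which liver genes differ without Chrebp after 2 weeks of fructose. Known ChREBP targets, genes of fatty acid synthesis and fructose breakdown, and male-biased liver genes were lower in the null pool. Genes of cholesterol synthesis, the cell cycle, the NRF2 response, the integrated stress response and the acute phase response were higher. In all, 236 genes were higher and 166 lower by at least 2-fold among 11631 above the floor. With the same trend removed, the split was 140 higher and 225 lower. Quantile normalization gave 181 and 180, and a floor at the 75 percentile 87 and 110. Against the 3-week WT pool as well, 114 of the 236 higher and 102 of the 166 lower genes passed 2-fold, with the null array in both differences. Simulated unchanged genes with a shared null array gave 14 and 17. The simulation holds noise only, so any trait of the null pool or its array, genotype or other, would also raise both counts. Among genes named below, Srebf1, Pfkfb3, Cidec and Acaca were under 2-fold against the 3-week pool.

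Of the 17 known ChREBP targets, 11 were at least 2-fold lower in the null pool, among them the targeted gene Mlxipl itself at -1.74, and 1 was at least 2-fold higher. Their median was -1.42 (random lists -0.10 to 0.17). Rgs16, a regulator of G protein signalling, was lower at -5.06 (a ratio of 33.3; probe set 17218321). Pklr, liver pyruvate kinase, was lower at -2.72 and G6pc, glucose-6-phosphatase, at -2.33. Fgf21 was the exception and was higher by 3.50. Among fatty acid synthesis genes 8 of 15 were at least 2-fold lower and the median was -1.07 (random lists -0.12 to 0.15), led by Me1 at -1.76, Srebf1 at -1.55, Acacb at -1.53 and Thrsp at -1.47. Against the 3-week pool that median was -0.70, with 4 of these 8 past 2-fold. Against chow, the null pool stood at -0.13 for fatty acid synthesis and -0.32 for ChREBP targets.

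In the fructolysis list, Tkfc and Khk, the kinases for glyceraldehyde and fructose, were lower at -1.84 and -1.65, and the median over 6 genes was -0.49 (random lists -0.22 to 0.30). Glycolysis genes had a median of -0.16 with 3 of 12 at least 2-fold lower, among them Pfkfb3 at -1.38 and Gpd2 at -1.25, and the median turned to 0.092 against the 3-week pool. In the triglyceride list Lpin1, a phosphatidic acid phosphatase, stood at -2.48, Pnpla3 at -1.42 and Cidec at 1.34, and the median was 0.03. Among gluconeogenesis genes Fbp1 stood at -1.18 beside G6pc, with a list median of -0.09. Pygl, liver glycogen phosphorylase, stood at -1.28 in the glycogen list, whose median of -0.23 turned to 0.014 against the 3-week pool.

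Cholesterol synthesis and SREBP2 target genes were higher in the null pool. The median was 1.06 (random lists -0.09 to 0.16), and 11 of 19 genes were at least 2-fold higher, 10 of them against the 3-week pool too. Sqle, squalene epoxidase, was higher by 2.00, Msmo1 by 1.95, Cyp51 by 1.83 and Lss, lanosterol synthase, by 1.82. Against chow the list median was 0.49, with 1 gene past 2-fold.

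Genes of the integrated stress response and the NRF2 response were higher in the null pool, while those of heat shock, endoplasmic reticulum chaperones and p53 signalling lay within random ranges. The integrated stress response list had a median of 0.65 (random lists -0.05 to 0.33), and 7 of 18 genes were at least 2-fold higher against each WT fructose pool. With levels below the floor set at the floor, 5 were so against the 2-week pool. The 7 counted as read included Slc7a11, the cystine transporter, at 3.54, Atf3 at 2.18, and the amino acid synthesis genes Asns and Psat1 at 1.78 and 1.61. Psat1 read below the floor in the 2-week WT pool, and with that level set at the floor it stands at 0.83, under 2-fold. Endoplasmic reticulum chaperones had a median of 0.07 with no gene past 2-fold. The NRF2 and glutathione list, which also holds Slc7a11, had a median of 0.82 (random lists -0.11 to 0.21), with 5 of 14 genes at least 2-fold higher, among them Cbr3 at 2.43, Srxn1 at 2.24 and Nqo1 at 1.99. Cbr3 and Slc7a11 read 2.85 and 2.67 in the 2-week WT pool, below the floor, and their differences are at least 1.76 and 2.69 with those levels set at the floor. The other probe set of Slc7a11 read 1.84 on average.

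Acute phase genes had a median of 0.46 in the null pool (random lists -0.10 to 0.14), with 5 of 19 at least 2-fold higher. Orm2 stood at 2.83, Saa2 at 2.75 and Orm3 at 2.25, but Orm3 stood at 0.09 against the 3-week pool. Chemokine and cytokine genes had a median of 0.40 (random lists -0.08 to 0.35), with Cxcl10 at 1.32 and Ccl6 at 1.23. That median turned to -0.18 with the floor at the 75 percentile, and against the 3-week pool the 2 genes stood at 0.84 and 0.95, under 2-fold. The macrophage marker list had a median of -0.03, with 2 of 17 genes at least 2-fold higher: Marco, a scavenger receptor, at 2.66 and Gpnmb at 1.40 (1.28 with the WT level set at the floor). Hepatocyte markers had a median of -0.07. Cell cycle genes had a median of 1.03 (random lists -0.06 to 0.37), and 8 of 16 were at least 2-fold higher, led by the replication licensing genes Mcm2 at 1.64 (1.53 with the WT level set at the floor), Mcm6 at 1.49 and Mcm4 at 1.34. With levels below the floor set at the floor the median was 0.71, with 7 past 2-fold. Against the 3-week pool it was 0.55 (random lists -0.13 to 0.36), with 5 of those 8 past 2-fold, and 0.37 with levels set at the floor, for which no random lists were drawn.

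Male-biased liver genes had a median of -1.15 in the null pool (random lists -0.10 to 0.21), and 11 of 15 were at least 2-fold lower against each WT fructose pool. Slco1a1, an organic anion transporter, stood at -6.24 (probe set 17472385), Hsd3b5, a steroid dehydrogenase, at -5.27, Elovl3 at -3.92 and Cyp4a12a at -3.06. Slco1a1 and Hsd3b5 read 2.83 and 2.20 in the null pool, below the floor, and with those levels set at the floor they stand at -5.55 and -3.95. Sex-linked genes moved as well. Xist, transcribed from the inactive X chromosome, stood at -1.53 in the null pool, and the Y-linked genes Eif2s3y, Kdm5d and Uty at 0.84, 0.76 and 0.53. These values lie on the side of more male RNA in the null pool, which argues against fewer males as the source of the lower male-biased genes. For female-biased genes, and for the size of the male-biased difference, genotype and the proportions of the sexes cannot be told apart in the Chrebp-null comparison. The female-biased list had a median of -0.58 (random lists -0.10 to 0.24), with 3 genes at least 2-fold higher and 3 lower. They ran from Sult1e1, estrogen sulfotransferase, at 4.82 (4.70 with the WT level set at the floor) to Cyp2c69 at -2.79. With levels below the floor set at the floor the median was -0.33, with 3 of 13 genes at least 2-fold higher and 2 lower. Cyp3a16 read below the floor on both arrays and was not assessed. Sult2a1, at 2.05, turned to -0.85 against the 3-week pool. Against that pool, with levels below the floor set at the floor, the female-biased median was -1.07, with 1 of 15 genes at least 2-fold higher and 10 lower.

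Other genes among the largest differences in the null pool were Sprr1a, a squamous epithelium gene, higher by 5.23, Cyp2c55 by 2.93, the transporter gene Abcc4 by 2.77 and Elovl7 by 2.58, or 2.29 with the WT level set at the floor. The other probe set of Cyp2c55 stood at -0.93, so that gene's direction is unsettled. Lower genes included Serpina4-ps1 at -5.70, Lepr at -3.32 and Egr1, an immediate early gene, at -2.40. Egr1 turned to 1.56 against the 3-week pool. In the bile acid list, Abcc4 and Slco1a4 were higher by 2.77 and 1.09 while Slco1a1 and Cyp8b1, sterol 12-alpha-hydroxylase, stood at -6.24 and -2.21. That list's median of -0.10 (random lists -0.10 to 0.15) turned to 0.24 against the 3-week pool. In the fatty acid oxidation list, where Fgf21 also stands, Acot2 and Pdk4 were higher by 1.75 and 1.30 and Vnn1 stood at -1.25, with a median of 0.14 (random lists -0.09 to 0.16).

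**Figure D2:**
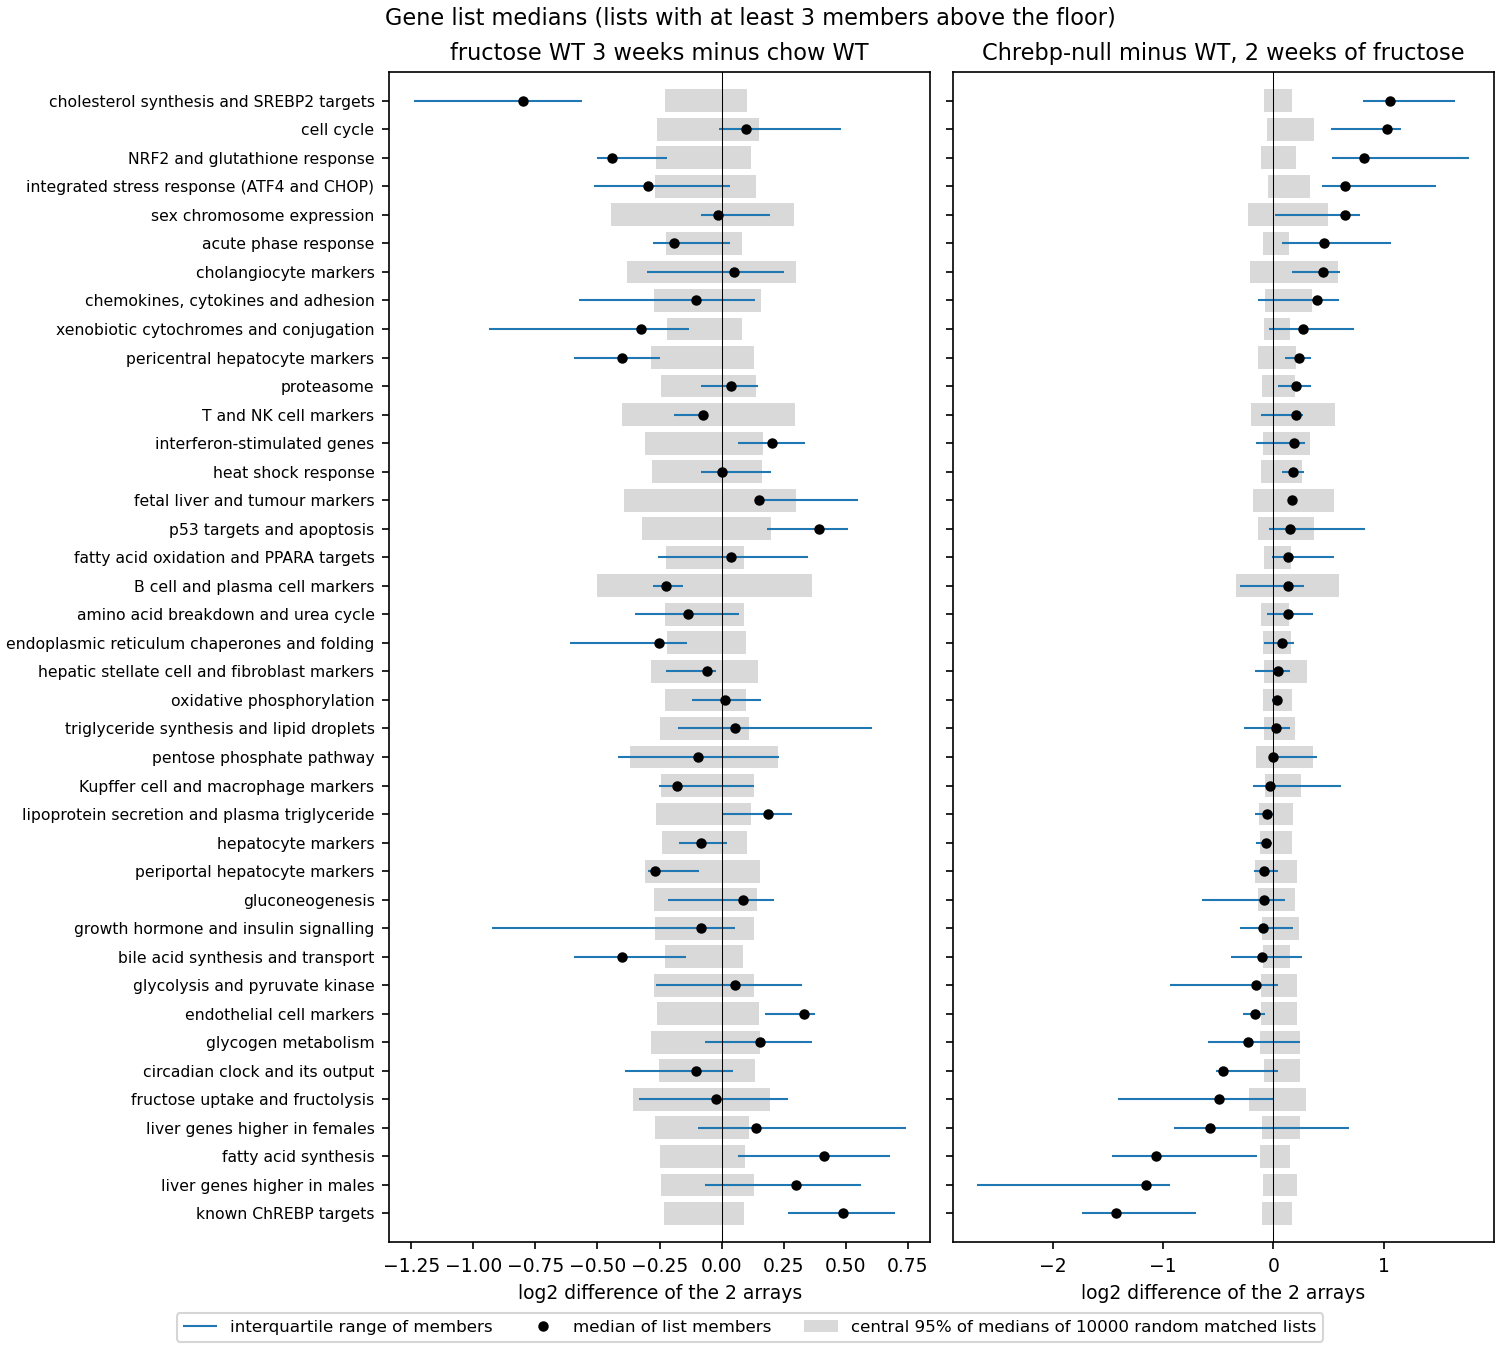
The log2 difference (horizontal axes) is plotted for each gene list (vertical axis) in the fructose comparison (left) and the Chrebp-null comparison (right): points are medians over members above the floor, lines their interquartile ranges and grey bars the central 95% of medians of 10000 random matched lists. Cholesterol synthesis lies at -0.80 on the left and 1.06 on the right, and known ChREBP targets at 0.49 and -1.42.

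Set against each other, the 2 comparisons ran in opposite directions for part of the genes. Of 11154 genes above the floor in both, 16 were higher on fructose and lower in the null pool, where 0.764 would be shared by independent lists of these sizes. They included Lepr (1.91 and -3.32), Pnpla3 (3.37 and -1.42), Fabp5 (2.43 and -1.29), Acaca (1.20 and -1.19), Me1 (1.18 and -1.76) and Sult1c2 (1.35 and -1.57). Another 22 were lower on fructose and higher in the null pool, against 2.40 for independent lists. These included Hmgcs1, Msmo1, Mvd, Cyp51, Lss and Acot2. Genes differing the same way numbered 4 in the higher direction (Akr1c18, Ect2, Cidec and Fgf21) and 6 in the lower (among them Gbp10, Bcl6, Egr1 and Tcf24), against 1.08 and 1.69. With levels below the floor set at the floor these were 3 and 4, and Fgf21, at 0.44 on fructose, was no longer among them. Ect2, a cytokinesis gene, was higher by 1.42 on fructose and 1.06 in the null pool, but stood at -0.0005 for null over the 3-week pool, and Akr1c18 at -1.05. Gbp10 stood at -1.70 and -1.58 (-0.89 and -0.77 with the other WT fructose pool), Bcl6 at -1.67 and -1.58 and Tcf24 at -1.54 and -1.15 (-0.52 and -0.13). Bcl6 turned to 0.16 with the 2-week pool over chow and to 0.25 for null over the 3-week pool.

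Over all 11154 genes the correlation across genes was weak, with Pearson's r of -0.140 and Spearman's rho of -0.095. Genes are not independent replicates, so no p-value goes with it. Unchanged genes simulated on 4 unrelated arrays gave r of 0.002. With the 2-week WT array in both comparisons r was -0.396 and with the 3-week WT array -0.569, but a shared array alone gave -0.523 and -0.525 in the simulation.

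**Figure D3:**
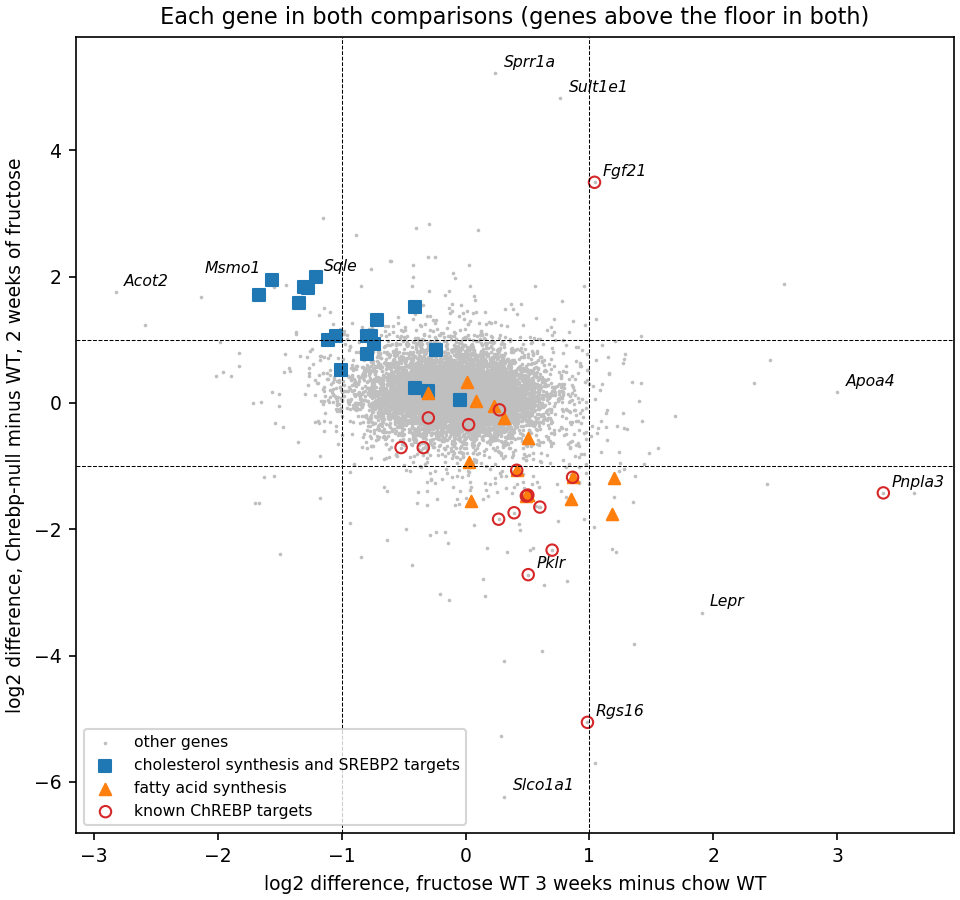
Each point is 1 of the 11154 genes above the floor in both comparisons, with the log2 difference of the fructose comparison on the horizontal axis and of the Chrebp-null comparison on the vertical axis. Dashed lines mark 2-fold, and the cholesterol genes Msmo1 (-1.57 and 1.95) and Cyp51 (-1.31 and 1.83) lie at the upper left, opposite Me1 (1.18 and -1.76) and Acaca (1.20 and -1.19).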

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

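Many probe sets that entered no gene-level comparison also differed by at least 2-fold, in the yardstick as well as in the comparisons. Among probe sets for which the annotation lists no gene, 719 of the 5361 above the floor differed by at least 2-fold in the fructose comparison, 499 higher and 220 lower. In the Chrebp-null comparison 929 of 5611 did, 420 higher and 509 lower. Between the WT fructose pools the counts were 507 higher and 525 lower of 5725, a larger share than in either comparison. Among probe sets listed with several genes, 17 of 848 differed by at least 2-fold on fructose and 48 of 828 in the null pool. Between the WT fructose pools 30 of these were higher and 9 lower of 844. What these probe sets measure is not analysed here, and no explanation of their differences was tested.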

How the results depend on the processing

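Across the alternatives, 79 of 116 counts and correlations stayed within the limits set (1.5 times for a count, 0.015 for r, its bootstrap SD over genes), as did 708 of 763 list medians and 802 of 924 named genes. For a list the limit was the spread of random lists, and for a gene 0.43, the SD over genes of the difference of the WT fructose pools. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The cause of the differences listed next was not tested, except that a stricter floor or threshold leaves fewer genes by construction. Signal over background limits the dim genes. Without a floor r was -0.119. With the floor at the 75 percentile, 40 genes were higher on fructose, 87 higher and 110 lower in the null pool, 127 differed between the WT fructose pools, 1 was higher and 2 were lower in both comparisons, and r was -0.213. The chemokine median turned to -0.18 and the sex chromosome median to -0.35 in the Chrebp-null comparison. Removal of the trend with level gave 140 higher and 225 lower genes in the null pool, and 93 and 105 on fructose in place of 75 and 136. It moved the median difference over all genes in the Chrebp-null comparison from 0.04 to -0.17. Over genes above the floor, the ones counted, it moved that median from 0.0987 to -0.0042. Quantile normalization gave 181 higher and 180 lower genes in the null pool. At 1.5-fold 418 genes were higher and 826 lower on fructose, 1065 and 441 in the null pool, and 1489 differed between the WT fructose pools. Overlaps were 73 (higher on fructose, lower in null), 130 (the opposite), 48 (both higher) and 31 (both lower). At 3-fold the counts were 14, 15, 46, 54 and 53, and the overlaps 1, 3, 1 and 0.

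With the 2-week WT array over chow, 37 genes were higher on fructose and lower in null, 39 the opposite, and r was -0.396. The simulated shared array gave 16, 15 and -0.523. The medians turned to 0.11 for NRF2, -0.36 for male-biased and -1.04 for female-biased genes. Among named genes Acot2 turned to 0.31, Akr1c18 to -0.36 (-0.0044 with its 2-week level set at the floor), Bcl6 to 0.16, Cyp3a16 to -5.35, Cyp3a44 to -3.01, Egr1 to 2.46, Sesn2 to 0.13, Sult2a3 to -0.71 and Sult3a2 to -2.96. Cyp3a16, Sult2a3 and Sult3a2 read below the floor there, and stood at -4.12, -0.61 and -2.03 with those levels set at the floor. With null over the 3-week WT array, 398 genes were higher, overlaps were 41, 75 and 1 (both lower), and r was -0.569. The simulated shared array gave 9, 17 and -0.525 for the opposite directions and r. The glycolysis median turned to 0.092, glycogen to 0.014 and bile acids to 0.24. Akr1c18 turned to -1.05, Bcl6 to 0.25, Ect2 to -0.0005, Egr1 to 1.56 and Sult2a1 to -0.85. With the mean of both WT fructose arrays, 38 genes were higher and 77 lower on fructose. The female-biased median turned to -0.39 and the bile acid median in the null comparison to 0.068. Cyp3a16 turned to -1.68, Cyp3a44 to -0.28, Egr1 to 0.48 and Sult3a2 to -0.40 on fructose. With the 2-week levels set at the floor Cyp3a16 stood at -1.06, and Sult3a2 at 0.064, no longer turned. Leaving out the listed sex-biased and sex-linked genes, an alternative chosen after seeing the data, gave 70 and 135 genes on fructose and 233 and 151 in the null pool. Levels below the floor set at the floor, chosen likewise, gave 58 and 128, 171 and 133, and r of -0.147. The Chrebp-null medians were then 0.71 for the cell cycle and -0.33 for female-biased genes.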

Other observations

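All tests of explanations in this part were chosen after the results were seen. Several lists not yet described stood outside the range of random lists. Markers of hepatocytes near the central vein had a median of -0.40 on fructose (random lists -0.29 to 0.13), with Rhbg, an ammonia transporter, and Lgr5, a receptor in Wnt signalling, both at -0.93, and 0.23 in the null pool (random lists -0.14 to 0.20). Against the 3-week pool the latter was 0.12, within its range (-0.17 to 0.33). Endothelial markers had medians of 0.33 on fructose (random lists -0.26 to 0.15) and -0.17 in the null pool (random lists -0.11 to 0.22), led by Lyve1 at 0.81 and -1.01 (-0.69 against the 3-week pool). Circadian genes had a median of -0.46 in the null pool (random lists -0.09 to 0.24), with Nr1d1 at -0.98 and Dbp at -0.84. Of the 14 genes 4 were above 0, among them Nfil3 at 0.94 and Arntl at 0.57. Against the 3-week pool the median was -0.25 (random lists -0.14 to 0.35), or -0.14 with levels below the floor set at the floor. Nr1d1 stood there at -0.59, and Dbp turned to 0.26. On fructose the circadian median was -0.10, with Dbp at -1.17. The hour of sampling is not given in the sources used here. Genes of p53 signalling had medians of 0.39 (random lists -0.32 to 0.20) and 0.15, with Cdkn1a higher by 1.10 on fructose and Btg2 lower at -1.11. Interferon-stimulated genes stood at 0.21 (random lists -0.31 to 0.17) and 0.19. With the 2-week pool over chow the p53 and interferon medians were 0.092 (random lists -0.26 to 0.18) and 0.04 (random lists -0.24 to 0.17), within range. Xenobiotic genes had a median of 0.27 in the null pool (random lists -0.09 to 0.15), where Cyp3a59 was higher by 1.88, and proteasome genes 0.21 (random lists -0.10 to 0.19). Against the 3-week pool both were within range, at 0.21 (random lists -0.12 to 0.24) and 0.084 (random lists -0.15 to 0.30).

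The remaining lists lay within their random ranges in both comparisons, or in the one named. In the order fructose and Chrebp-null, the medians were 0.02 and 0.03 for oxidative phosphorylation, 0.00 and 0.18 for heat shock, -0.06 and 0.04 for stellate cells and fibroblasts, 0.05 and 0.45 for cholangiocytes, -0.07 and 0.20 for T and NK cells, -0.22 and 0.13 for B and plasma cells, -0.27 and -0.08 for hepatocytes near the portal vein, and 0.15 and 0.17 for fetal liver and tumour markers. On fructose alone they were 0.04 for the proteasome, -0.19 for acute phase genes, -0.10 for chemokines, 0.10 for the cell cycle, -0.18 for macrophages, -0.08 for hepatocytes and -0.01 for sex chromosome genes. With the 2-week pool over chow the macrophage median turned to 0.25 (random lists -0.18 to 0.14), above its range. The cholangiocyte median was then 0.35 (random lists -0.46 to 0.29), also above, and the sex chromosome median 0.39. In the null pool alone the medians were -0.01 for the pentose phosphate pathway, 0.13 for amino acid breakdown, -0.06 for lipoproteins and -0.10 for growth hormone and insulin signalling. The sex chromosome list, in which Xist and the Y-linked genes move apart, had a median of 0.65 in the null pool. Neutrophil markers rested on 1 gene above the floor in each comparison, not the same one (0.086 with its chow level set at the floor, and 0.22), pancreas markers on 2 and 1 (-0.20 and -0.07) and adipose markers on 2 (-0.09 and -0.20). Of 10 red blood cell markers 1 was measured, and it lay below the floor.

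Male-biased liver genes were lower in the Chrebp-null pool. Fewer males in that pool is argued against by the Y-linked genes, whose median difference was 0.76, from 0.53 to 0.84, on the side of more male RNA. Xist, at -1.53, lay on the same side. An unusual 2-week WT pool is argued against by the 3-week pool, against which the list stood at -1.79 with an upper quartile of -1.42. Loss of ChREBP may contribute to the -1.15, but with 1 null pool it cannot be told apart from other differences between the pooled animals.

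Female-biased liver genes were higher in the 3-week than in the 2-week WT fructose pool, with a median of 1.48 and 9 of 15 at least 2-fold higher. Cyp3a16, which read 2.28 in the 2-week pool, below the floor, differed by at least 6.11 with that level set at the floor, Cyp3a44 by 5.47 and A1bg by 3.12. A larger share of females in the 3-week pool would need Xist to differ by about as much, and Xist differed by 0.21, below the lower quartile of the list (0.43), while male-biased genes were also higher, by 0.72. The Y-linked genes Eif2s3y, Kdm5d and Uty stood at -0.51, -0.35 and -0.20 for the 3-week minus the 2-week pool. With Xist they lie on the side of more female RNA in the 3-week pool, so a smaller difference in the share of females stays open. No experiment or array batch is given for the pools in the sources used here. If the chow and 3-week pools were handled apart from the 2-week pools, a difference in mice or batch would go with the chow pool. Its median was 1.04 above the 2-week pool while the 3-week pool was 0.14 above chow. In that case the values of the 2-week pool over chow would also carry such a difference. A response that differs between 2 and 3 weeks of fructose stays open and was not tested.

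Cell cycle genes were higher in the Chrebp-null pool, with a median of 1.03, or 0.71 with levels below the floor set at the floor. More leukocytes in the null livers stays open. The median of 26 leukocyte markers above the floor was 0.067 with an upper quartile of 0.29, but against the 3-week pool it was 0.23 with an upper quartile of 0.48. The 17 macrophage markers stood there at 0.37 (random lists -0.10 to 0.32) with an upper quartile of 0.76, above the cell cycle median of 0.55. An unusually low 2-week WT pool is not settled either. Against the 3-week pool the cell cycle list had a lower quartile of 0.21, within the range of random lists (-0.13 to 0.36). The chow pool goes against that explanation. The 2-week WT pool stood at -0.14 over chow, within its range (-0.27 to 0.13). The null pool stood at 0.62 over chow with a lower quartile of 0.37, above its range (-0.13 to 0.28), though without a value at the floor. With 1 null pool, loss of ChREBP was not tested as an explanation and stays open.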
